A study of Homo sapiens with 6 samples.

How the data were processed

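RNA was measured in KhES-1, an established human embryonic stem cell line, modified to carry a doxycycline-inducible short hairpin RNA (shRNA) against AKAP13 and an overexpressed BCL2L1 protein product, Bcl-XL. Per the labels' protocols, colonies grew on Matrigel in medium conditioned by mouse embryonic fibroblasts with 10% serum replacement under 2% CO2, and treated cultures received doxycycline at 1 µg/ml for 72 hours. Libraries were made from 1 µg of total RNA with an Illumina TruSeq kit and sequenced on a HiSeq instrument. The series holds 6 libraries, 3 untreated and 3 doxycycline-treated, described as biological replicates.

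Each file holds 1 library with 24011 rows, 22623 distinct gene symbols and 1804 rows whose symbol is shared with another row. The deposited signal is in CPM, read counts scaled to library size, per the file headers. Every value was a whole multiple of a single step per library within a tolerance of 0.01 reads (100% of values), so read counts could be recovered. The recovered totals were 19302336, 28078103 and 26234364 reads in untreated libraries 1, 2 and 3 and 22120294, 23807652 and 23017884 in doxycycline-treated libraries 1, 2 and 3. The deposited values imply library scaling factors between 0.956 and 1.02 whose product is 1. Per the submitters' processing notes, bcl2fastq 1.8.3, FastQC 0.10.1, TopHat2 2.0.8b, Cuffdiff, Cufflinks 2.1.1, edgeR 3.2.4 and the build hg19 were used; which of these tools produced the values is not given in the sources used here. No gene of the mitochondrial genome was analysed here, since none of the 13 symbols in that list matched a row.

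The tests, the gene lists, the rule for named genes and the first set of other settings were chosen before the data were examined. Values were tested as log2(CPM + 1) with limma 3.58.1 in R 4.3.3 (linear model without a replicate term, empirical Bayes with a variance trend, two-sided), with Benjamini-Hochberg adjustment over all 13779 genes that reached 1 CPM in at least 3 libraries; 10232 rows stayed below that filter. The threshold was an adjusted p of 0.05. Fold changes in log2 are on the log2(CPM + 1) scale, which understates the change of genes near 1 CPM, while folds without log are ratios of mean CPM. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 31 of 32 lists with at least 5 tested members. A member given by several rows was taken from the row with the highest mean.

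Named genes followed 4 parts of the rule. They were AKAP13 and BCL2L1; the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold with a mean of at least 5 CPM and no overlap between the groups; up to 4 members past the threshold with the smallest adjusted p and up to 2 others with the highest mean from each list; and POU5F1, NANOG, SOX2, CTGF, CYR61, ANKRD1, YAP1, WWTR1 and RHOA. The rule gave 190 tested genes, and every one entered the comparison of processing settings. The text names a subset: the first 6 rises and first 6 falls by log2 change, and for each list it describes the members past the threshold that the rule gives, except that some genes and 1 list are not reported here. Members not past it, genes given for their sequence match and the genes plotted were picked after their values were seen. Genes of the 10 groups that were added later were also chosen after their values were seen. Of the 13779 genes tested, 52.4% had no overlap between the groups, against 10% by chance for 3 against 3 libraries.

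On simulated reads drawn from the untreated and treated libraries' means and depths, the limma test ran on 13660 genes for this comparison. It recovered 12% of 50 genes changed 1.5-fold, 70% of 50 changed 2-fold, 92% of 50 changed 3-fold and 96% of 50 changed 4-fold, and 2.88% of its calls were unchanged genes. That run made 139 calls, against 4617 in the data, so its adjusted threshold was stricter. Genes were drawn independently, without noise shared across genes. Its shares therefore do not carry over to the data. Counting noise is small at this depth for genes well above the filter, since 1 read was worth 0.0353 to 0.0508 CPM, but not for genes near 1 CPM. No library was a copy of another: chi-square per degree of freedom between replicates lay between 4.98 and 87.0.

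Replicate numbers are given by the labels in both groups, which do not say what a number stands for. Whether they pair the libraries was checked from the values: deviations from the group means correlated at r = 0.62, 0.59 and 0.32 across genes for the libraries numbered 1, 2 and 3. All lay over 0.1, so the numbers were used as a block, from the data and not from the design. Untreated library 3 correlated better with treated library 2 (0.37) than with its own number, and treated library 3 better with untreated library 2 (0.45). Pairing 2 and 3 the other way would thus pass the same limit. Deviations within a group sum to 0, so the 3 correlations are not independent. Whether the libraries numbered 2 and 3 are pairs could therefore not be settled.

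The settings varied were 3 other scalings, 2 pseudocounts, 2 filters, 2 variance models, the replicate number as a block, leaving out each library, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, and camera with an estimated correlation. After the data were seen, 3 more were added: leaving out both libraries numbered 1, reads scaled to library size without the deposited factors, and leaving out genes with a sequence match described next.

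Sequence matches in 3' untranslated regions (3' UTRs) were sought in the longest annotated 3' UTR of each gene in GENCODE v29, matched by gene identifier and then by symbol. That annotation is on GRCh38 while the files use hg19, so no coordinates are printed. Of 13774 tested symbols, 13102 had a 3' UTR, and 13012 of these had at least 50 bases. For each of 16384 heptamers (7-base sequences), the log2 fold change was regressed on presence in the 3' UTR, with UTR length and GC content as covariates. In 5 simulated runs with a heptamer planted at a log2 change of -0.2, the planted one ranked first in 5, and on shuffled values the largest t was 4.08 in size.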

Results

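The transcriptome of KhES-1 human embryonic stem cells was compared between 3 untreated cultures and 3 cultures treated with doxycycline, which induces an shRNA against AKAP13. AKAP13, also called AKAP-Lbc, encodes an anchoring protein for protein kinase A. All cells overexpressed Bcl-XL, the anti-apoptotic product of BCL2L1, which the design gives as a means to limit cell loss. The comparison asks which genes differ between cells with and without the induced hairpin. No library of cells treated with doxycycline but lacking the hairpin was analysed here. Depth ranged from 19302336 to 28078103 reads per library, and values are CPM as mean ± SD with n = 3 per group.

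AKAP13 fell from 36.5 ± 1.23 CPM to 14.3 ± 1.88 CPM, a 2.55-fold drop that was present in each treated library (12.8, 16.4 and 13.7 CPM, against 35.6, 37.9 and 36.0 CPM untreated). The log2 change was -1.30 (SE 0.11, limma adjusted p = 0.000652). BCL2L1 stood at 294 ± 21.2 CPM untreated and 253 ± 32.1 CPM treated, which did not pass the test (adjusted p = 0.148) but did with the replicate number as a block (adjusted p = 0.0165). The values sum the endogenous gene and any transgene transcript that shares its sequence.

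Treated cells differed widely from untreated cells. Of 13779 genes tested, 4617 passed the threshold, 2178 higher and 2439 lower, and 809 of them changed at least 2-fold, 385 higher and 424 lower. The first 6 rises by log2 change were those of DHRS2, LIPG, CEBPD, STMN4, PLAT and CADM2. DHRS2, a short-chain dehydrogenase, rose from 3.32 ± 0.76 to 49.2 ± 3.36 CPM (14.8-fold), STMN4, a neuronal stathmin, from 1.60 ± 0.80 to 17.5 ± 3.51 CPM, PLAT, tissue plasminogen activator, from 9.40 ± 2.56 to 64.9 ± 10.7 CPM, and CADM2, a synaptic adhesion molecule, 6.66-fold. LIPG, endothelial lipase, was at 556, 27.9 and 148 CPM in treated libraries 1, 2 and 3 (adjusted p = 0.0384) and CEBPD, a transcription factor, at 165, 20.7 and 54.9 CPM (adjusted p = 0.0168). The LIPG call ended without untreated library 1, 2 or 3 or treated library 3 (adjusted p = 0.0662, 0.121, 0.112 and 0.101) and without the filter on low values (adjusted p = 0.0517), and the CEBPD call without untreated library 2 or 3 or treated library 3 (adjusted p = 0.0602, 0.0666 and 0.0531). Of the 12 largest rises, 5 lost the call when 1 library was left out, the others being HMOX1, GABRB2 and LOC100130093, while 0 of the 12 largest falls did. The rises spanned 5.26 to 19.3-fold and the falls 5.12 to 14.9-fold.

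The first 6 falls by log2 change were those of GNB4, AMOTL2, CYP26A1, CTGF, MRPL37 and BLVRA. GNB4, a G protein beta subunit, fell 10.6-fold from 45.8 ± 1.29 to 4.32 ± 0.52 CPM, and AMOTL2, an angiomotin that binds YAP1, fell 11.6-fold to 2.30 ± 0.22 CPM. CYP26A1, which degrades retinoic acid, fell 14.9-fold from 13.6 ± 3.97 CPM. CTGF fell 8.19-fold, MRPL37, a mitochondrial ribosomal protein, 7.82-fold, and BLVRA, biliverdin reductase, 8.96-fold. The heptamer TCCTCTA or its shifted form CCTCTAA lies in the 3' UTR of 4 of the 12 largest falls (GNB4, AMOTL2, PDPN and POLR3G), of 2 among the 10 of the 12 largest rises that had a searched 3' UTR, and of AKAP13. One of the 2 was present in 44.2% of 407 genes that fell at least 2-fold, in 9.84% of 376 that rose at least 2-fold and in 16.3% of all 13009 genes with a searchable 3' UTR.

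With the replicate number as a block, 7251 genes passed, among them all 4617. Leaving out untreated library 2, untreated library 3 or treated library 3 lowered the count to 2465, 1969 and 2279. The libraries numbered 1 stood apart from the others of their group along the second principal component (20.9% of variance), at 23.6 untreated and 20.3 treated, against -6.57 and 0.89 untreated and -25.2 and -13.1 treated. Without both of them, a choice made after seeing the data, 7366 genes passed and 671 changed at least 2-fold. Of the 190 genes chosen by the rule, 129 passed, and 37 of these lost the call when 1 library was left out.

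**Figure D1:**
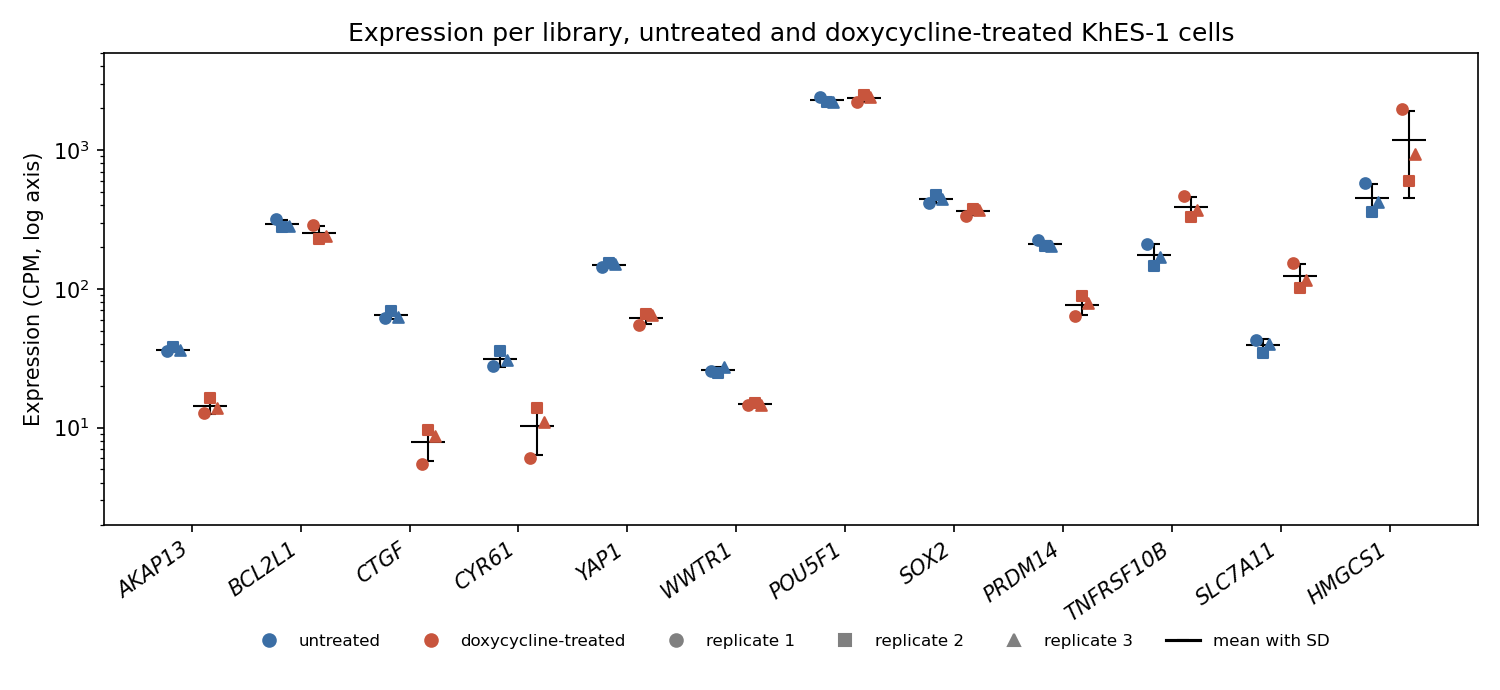
Expression of 12 genes in CPM (log axis) in each of 3 untreated (blue) and 3 doxycycline-treated (red) libraries, with marker shapes for replicate numbers and black bars for the mean and SD. AKAP13, CTGF, CYR61, YAP1, WWTR1 and PRDM14 lie lower in all 3 treated libraries, POU5F1 overlaps between the groups, and HMGCS1 spans 601 to 1989 CPM within the treated group.

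Several Hippo pathway genes, and the YAP/TAZ target genes CTGF and CYR61, were lower. YAP1, the transcriptional coactivator of the pathway, fell 2.41-fold from 149 ± 4.59 to 61.8 ± 5.93 CPM (log2 -1.26, SE 0.09, adjusted p = 0.000424). WWTR1, which encodes the related coactivator TAZ, fell 1.75-fold from 25.9 ± 1.32 to 14.8 ± 0.31 CPM. CTGF, a secreted matrix protein induced by YAP1, fell 8.19-fold from 64.7 ± 4.30 to 7.90 ± 2.18 CPM (log2 -2.91, SE 0.19, adjusted p = 0.000325), and the related CYR61 fell 3.06-fold from 31.3 ± 3.86 to 10.2 ± 3.94 CPM. AJUBA, a LIM protein of the pathway, fell 2.88-fold. ANKRD1 was below the filter, with 27, 24 and 36 reads in the untreated and 16, 4 and 9 reads in the treated libraries. Of 21 tested Hippo pathway components, 11 fell and 2 rose, the same numbers adjusted over the list alone (11 and 4 with the block). The list passed (camera adjusted p = 0.0421), but not with the block (adjusted p = 0.0683), without treated library 1 (adjusted p = 0.0615) or 3 (adjusted p = 0.0534), without both libraries numbered 1 (adjusted p = 0.0658), or with an estimated correlation (adjusted p = 0.559). The heptamer or its shifted form lies in the 3' UTR of 9 of the 21, YAP1, WWTR1 and AMOTL2 among them, and of 6 of the 11 that fell. With such genes left out, 12 members remained, of which 5 fell and 2 rose, and the adjusted p was 0.543 with fewer members tested.

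The list of 19 tested YAP/TAZ targets was mixed. AMOTL2, CTGF, CYR61 and AXL, a receptor tyrosine kinase (2.17-fold), were among 7 that fell, while GADD45A, also a DNA damage response gene, was among 3 that rose (2.40-fold), with the same numbers adjusted over the list alone and 7 of each with the block. Its median log2 change was 0.03, its mean -0.29 and its camera test not past the threshold (adjusted p = 0.689, lower). The heptamer or its shifted form lies in the 3' UTR of 6 of the 19 and of 3 of the 7 that fell, AMOTL2 among them. AXL has a match in the rest of the transcript, while CTGF and CYR61 have none. With genes holding a 3' UTR match left out, 13 members remained, of which 4 fell and 2 rose.

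Pluripotency genes split. POU5F1, which encodes OCT4, was at 2283 ± 93.8 CPM untreated and 2372 ± 147 CPM treated (adjusted p = 0.611, and 0.0439, higher, without both libraries numbered 1). NANOG was at 273, 168 and 207 CPM in the untreated and 209, 138 and 159 CPM in the treated libraries 1, 2 and 3 (adjusted p = 0.235, and 0.00347 with the block). SOX2 fell 1.23-fold from 446 ± 29.9 to 361 ± 20.7 CPM (adjusted p = 0.0297); the call ended without untreated library 2 (adjusted p = 0.106), untreated library 3 (adjusted p = 0.111) or treated library 3 (adjusted p = 0.0845). PRDM14, a transcription factor of the pluripotency network, fell 2.73-fold from 210 ± 11.7 to 77.0 ± 12.2 CPM, and GDF3, a TGF-beta family ligand, fell 2.09-fold. FGF2, a growth factor for these cells, fell 1.90-fold and LIN28B, an RNA-binding protein, 1.87-fold, both with the heptamer in the 3' UTR. GDF3 and NANOG have a match in the 5' UTR or coding sequence. Of 24 tested genes of core and primed pluripotency, 11 fell and 0 rose, or 13 and 0 adjusted over the list alone, 15 and 1 with the block, and 16 and 4 without both libraries numbered 1. The list passed as lower (camera adjusted p = 0.00157; adjusted p = 0.559 with an estimated correlation).

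Among stress-response genes, p53 and ATF4 targets past the threshold were nearly all higher, while of 6 heat shock genes past it 5 were lower. SESN2, a stress-induced sestrin, rose 1.60-fold, BBC3, the pro-apoptotic PUMA, 1.60-fold from 98.6 ± 9.44 to 158 ± 11.2 CPM, TNFRSF10B, a death receptor, 2.21-fold from 176 ± 33.1 to 388 ± 70.6 CPM, and SESN1 1.56-fold. MDM2, a classical p53 target with the shifted heptamer in its 3' UTR, was at 270 ± 9.83 and 273 ± 42.5 CPM (adjusted p = 0.979). Of 22 p53 targets, 12 rose and 0 fell, or 13 and 0 adjusted over the list alone (camera adjusted p = 3.29e-05; adjusted p = 0.559 with an estimated correlation). With genes holding a 3' UTR match left out, 16 of these targets remained, of which 12 rose. Among 25 targets of ATF4 and the integrated stress response, 11 rose and 1 fell, or 14 and 2 adjusted over the list alone and 15 and 3 with the block (camera adjusted p = 0.00157; adjusted p = 0.559 with an estimated correlation). MTHFD2, a mitochondrial folate enzyme, rose 1.78-fold to 597 ± 13.6 CPM, and SLC7A11, the cystine transporter, rose 3.16-fold to 123 ± 26.5 CPM. SESN2 and GDF15 belong to both the p53 and the ATF4 list. The gene that fell, CARS, encodes cysteinyl-tRNA synthetase. SLC7A11 and CARS both have a heptamer match in the 5' UTR or coding sequence. Within the BCL2 family, 4 of 16 tested regulators rose and 2 fell, the same numbers adjusted over the list alone (5 and 4 with the block), and the list did not pass (adjusted p = 0.689). BCL2L11, the pro-apoptotic BIM, rose 2.25-fold and PMAIP1, the pro-apoptotic NOXA, 1.60-fold. BOK, another family member, fell from 35.4 ± 1.99 to 23.6 ± 3.66 CPM, a call that ended without untreated library 2 (adjusted p = 0.0652) or 3 (adjusted p = 0.0539).

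Of 12 tested heat shock genes, 5 fell and 1 rose, the same numbers adjusted over the list alone, and the list did not pass (camera adjusted p = 0.144, lower), but it did without both libraries numbered 1 (adjusted p = 0.0321). HSP90AA1, a cytosolic chaperone, fell 2.38-fold from 2091 ± 370 to 877 ± 133 CPM, with the heptamer in its 3' UTR, and DNAJA1, a co-chaperone, 1.46-fold. CHORDC1 fell 1.46-fold, a call that ended without untreated library 3 (adjusted p = 0.0556) or treated library 3 (adjusted p = 0.0501). HSPH1 fell 1.48-fold, a call that ended without untreated library 2 or 3 or treated library 3 (adjusted p = 0.0986, 0.105 and 0.0616). HSPA8, which fell (adjusted p = 0.0317), and BAG3, the gene that rose (adjusted p = 0.0290), were chosen after their values were seen, and both calls ended without untreated library 1, 2 or 3 or treated library 3. The adjusted p was then 0.0528 to 0.124 for HSPA8, whose call also ended with quantile normalization (0.0535), without the filter (0.0943) and without a variance trend (0.0538), and 0.0551 to 0.0867 for BAG3.

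More matrix and adhesion genes rose than fell. COL5A2, a fibrillar collagen, rose 3.11-fold from 27.0 ± 3.42 to 84.0 ± 6.69 CPM, COL5A1, its partner chain, 2.21-fold, ITGAV, an integrin subunit, 1.78-fold, and NID1, a basement membrane protein, 2.81-fold from 111 ± 7.77 to 313 ± 104 CPM. FN1, fibronectin, was at 492 ± 193 and 819 ± 411 CPM (adjusted p = 0.206, and 0.000944 with the block). Of 24 tested genes of this list, 12 rose and 3 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.00204; adjusted p = 0.507 with an estimated correlation).

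Cholesterol synthesis genes had large spread within the treated group. SREBF2, the transcription factor that drives the pathway, rose 1.79-fold (adjusted p = 0.0172), a call that ended without untreated library 2 (adjusted p = 0.0660) or 3 (adjusted p = 0.0716). MVD, an enzyme of the pathway, rose from 56.2 ± 7.62 to 168 ± 92.8 CPM (adjusted p = 0.0224), which ended without untreated library 1, 2 or 3 or treated library 3 (adjusted p = 0.0509, 0.0780, 0.0829 and 0.0600). HMGCS1, an early enzyme of the pathway, was at 577, 355 and 421 CPM in the untreated and 1989, 601 and 941 CPM in the treated libraries 1, 2 and 3, and did not pass (adjusted p = 0.0596, and 0.00334 with the block). Library 1 was thus the highest of its group in both. Of 21 tested genes, 4 rose and 1 fell, or 13 and 1 adjusted over the list alone, and 15 and 1 with the block. The list passed as higher (camera adjusted p = 0.00204; adjusted p = 0.796 with an estimated correlation).

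More nuclear-encoded respiratory chain genes fell than rose. UQCRC1, of complex III, fell 3.90-fold from 197 ± 22.1 to 50.6 ± 12.9 CPM and NDUFA4 fell 2.68-fold from 212 ± 14.4 to 79.0 ± 8.43 CPM, both with the heptamer in the 3' UTR. Of complex II, SDHB fell 1.58-fold and SDHA rose 1.37-fold. Of 22 tested genes, 9 fell and 2 rose, or 10 and 2 adjusted over the list alone, and 16 and 2 with the block (camera adjusted p = 0.00322; adjusted p = 0.796 with an estimated correlation).

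Actin genes moved in both directions. Of 29 tested genes of the SRF/MRTF and actin list, 4 rose and 6 fell, the same numbers adjusted over the list alone and 7 and 11 with the block, and the list did not pass (camera adjusted p = 0.580). RHOA was at 549 ± 13.8 and 508 ± 36.8 CPM (adjusted p = 0.277). ACTA2, smooth muscle actin, rose 2.50-fold and SRF, the transcription factor the list is named for, fell 1.62-fold. MYH9, nonmuscle myosin, rose 1.43-fold and TPM1, a tropomyosin, fell 1.89-fold. Both SRF and TPM1 have the shifted heptamer in the 3' UTR. With genes holding a match left out, 24 members of the actin list remained, of which 4 rose and 3 fell. VIM, vimentin, rose 2.45-fold as 1 of 5 risen and 2 fallen genes among 15 of the epithelial to mesenchymal list (7 and 2 adjusted over the list alone, 8 and 2 with the block; camera adjusted p = 0.131, and 0.0289 without the filter on low values). TWIST1 rose 4.79-fold. CDH2, N-cadherin, rose 1.62-fold and ESRP1, an epithelial splicing regulator with the heptamer in its 3' UTR, fell 1.45-fold. Both calls ended without untreated library 1, 2 or 3 or treated library 3, with adjusted p from 0.0551 to 0.0988 for CDH2, also without treated library 2, and from 0.0640 to 0.0855 for ESRP1.

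In total, 7 of 31 lists passed, and 0 passed in camera with an estimated correlation, where 1 had an unadjusted p under 0.05. The other 24 lists had camera adjusted p between 0.120 and 0.939. Their 359 tested entries held 71 that rose and 56 that fell, or 116 and 99 with the block. They covered markers of neuroectoderm, mesoderm, endoderm, trophoblast, neural crest and fibroblasts as well as cell cycle, WNT, FGF and TGF-beta targets. In 8 of them, YAP/TAZ targets included, the median, mean and test differed in sign.

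**Figure D2:**
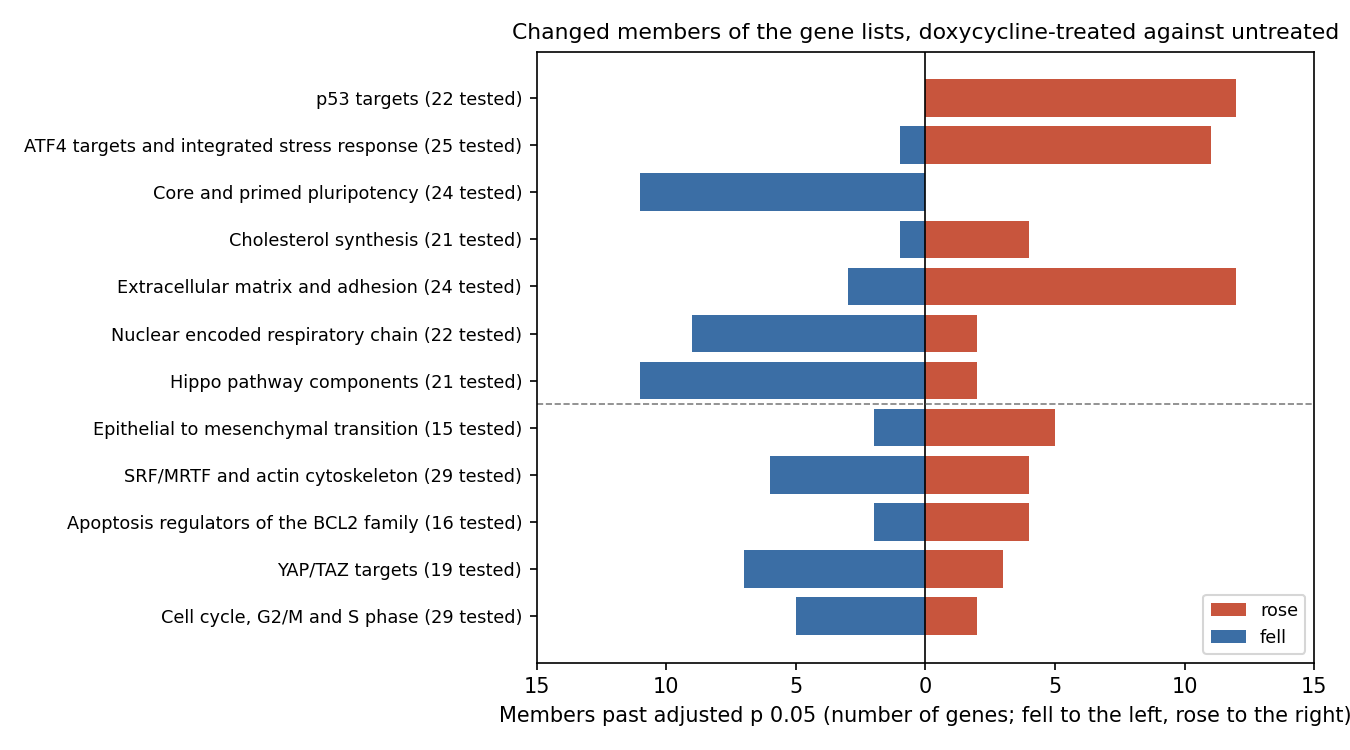
Numbers of tested members that rose (red, to the right) or fell (blue, to the left) past an adjusted p of 0.05 in 12 of the gene lists, with the number tested in brackets. The 7 lists above the dashed line passed camera at the preset correlation; the p53 targets show 12 rises and 0 falls, and core and primed pluripotency 0 rises and 11 falls.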

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

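The 3 alternatives named as added were chosen after the results were seen. AKAP13 stayed past the threshold in all 20 alternatives, with log2 changes from -1.39 to -1.11 and an adjusted p of at most 0.00832. Leaving out each library gave 1969 to 5152 genes changed, 655 to 1072 changed at least 2-fold, 6 to 7 lists and log2 changes of AKAP13 from -1.39 to -1.23. The count of 4617 rose to 7251 with the replicate number as a block, to 7366 with both libraries numbered 1 left out (added) and to 11834 with library quality weights, whose estimation did not converge and put a weight of 257 on treated library 3. The other alternatives left it between 3568, where genes with the heptamer in the 3' UTR were left out (added) and fewer genes tested, and 5434. The count of 809 became 437 with a pseudocount of 5, which shrinks log2 changes by construction, and 1119 with a pseudocount of 0.1. On recovered reads it was 1168 with edgeR and 1254 with DESeq2. Both work without the pseudocount of 1, which understates changes of genes near 1 CPM. Whether that is the whole cause was not tested. The 7 lists became 0 with an estimated correlation, where limma's camera gave 1 unadjusted p under 0.05. Of 129 called genes among the 190 the rule gave, 37 lost the call in some setting, each when 1 library was left out, and 49 others gained one, 27 of them with the block. The block ended the call of the Hippo list and of no gene, and among later groups it added the proteasome; it changed no other list's call. The Hippo list also missed the threshold with quantile normalization, quality weights and unscaled reads (adjusted p = 0.0570, 0.120 and 0.0565). Among lists not past the threshold, the epithelial to mesenchymal and interferon lists passed without the filter (adjusted p = 0.0289 and 0.0366), and heat shock without both libraries numbered 1 (adjusted p = 0.0321). For lost calls without a stated reason, the cause was not tested. With quality weights, KRT18 (log2 -0.0506) and CCND1 (0.1439), not past the threshold otherwise, turned sign and passed. In the simulation, with few changed genes and independent noise, the test recovered 12% of 1.5-fold and 70% of 2-fold changes. These shares do not carry over to the data, and no setting varied depth alone.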

Other observations

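The 10 gene groups of this and the next paragraph, their named genes, the heptamer tests by library and by match length, and the tests on the libraries numbered 1 along the treatment axis were chosen after the results were seen. More lysosomal genes rose than fell: of 30 tested, 14 rose and 2 fell, or 16 and 2 adjusted over the list alone (camera adjusted p = 0.00314 over the 10 groups; adjusted p = 0.761 with an estimated correlation). NPC1, which exports cholesterol from lysosomes, rose 2.52-fold from 57.3 ± 5.96 to 144 ± 54.4 CPM (n = 3 per group), and CTSD, a lysosomal protease, rose 1.69-fold and NEU1, a sialidase, 3.48-fold (not past the threshold without untreated library 2 or 3, adjusted p = 0.0550 and 0.0573), while ATP6V1A, a proton pump subunit with the heptamer in its 3' UTR, fell 3.34-fold. Genes of vesicle transport between endoplasmic reticulum and Golgi followed with 10 rises and 2 falls among 21 (adjusted p = 0.0339; adjusted p = 0.790 with an estimated correlation). SEC24A, a coat protein of these vesicles, rose 1.85-fold, SEC31A, another, 2.12-fold, and KDELR1, a retrieval receptor, fell 2.22-fold. The SEC31A call ended without untreated library 2 or 3 (adjusted p = 0.0523 and 0.0545), and the group's without untreated library 2 (adjusted p = 0.0893), without treated library 1 (adjusted p = 0.0740), with quantile normalization (adjusted p = 0.0712) and with edgeR on recovered reads (adjusted p = 0.0537).

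Ribosome biogenesis genes past the threshold were lower: of 19 tested, 8 fell and 0 rose, and 16 fell with the replicate number as a block (adjusted p = 0.00191; adjusted p = 0.761 with an estimated correlation). NOP58, of the small nucleolar ribonucleoproteins, fell 1.61-fold from 87.4 ± 4.04 to 54.4 ± 2.30 CPM and NAT10, an RNA acetyltransferase, 2.14-fold. Of 22 mitochondrial ribosomal proteins, 5 fell and 0 rose, or 11 and 1 with the block (adjusted p = 0.0337; adjusted p = 0.761 with an estimated correlation), a call that ended without untreated library 2 (adjusted p = 0.0893) or treated library 1 (adjusted p = 0.0727). The 5 include MRPL37, named above among the largest falls, so the group is not separate from that result. MRPL37 has a heptamer match in its 5' UTR or coding sequence. MRPL4 fell 1.58-fold, but not past the threshold without untreated library 2 or 3 (adjusted p = 0.0662 and 0.0626). Not past the threshold were NRF2 targets (7 rose and 2 fell of 15, adjusted p = 0.0605, but past it in 5 other settings with adjusted p from 0.0113 to 0.0452), proteasome subunits (0 and 2 of 23, adjusted p = 0.212, but 0.0448 with the block, 0.0362 without untreated library 1 and 0.0498 without treated library 2), the small RNA pathway (1 and 4 of 13, adjusted p = 0.402), protocadherins (2 and 3 of 16, adjusted p = 0.627), cytosolic tRNA synthetases (3 and 3 of 20, adjusted p = 0.942) and mitochondrial transcription (1 and 0 of 7, adjusted p = 0.942).

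The steep falls carried a sequence signature. Over 16384 heptamers, TCCTCTA in the 3' UTR had the lowest t, -17.5 (1402 genes, log2 difference -0.27), against 6.21 for the highest (TGCACTT); it ranked first in each treated library alone (t of -13.2, -19.4 and -18.2) and was near 0 in each untreated library against the others (-0.41, 0.19 and 0.63). Mean log2 changes were -0.31 with the longest match of 8 bases, -0.17 with the heptamer, -0.12 with its shifted form and 0.03 with no match, and among genes without a match in the 3' UTR, one in the rest of the transcript went with lower values too (t = -8.12). This is consistent with off-target repression by the hairpin's RNA acting like a microRNA, although the hairpin's sequence was not used here; the heptamer is in 2 of 5 AKAP13 transcripts, as such a guide needs, but 53.1% of all heptamers are in at least 1. Open remain the loss of AKAP13, doxycycline and a change of an endogenous small RNA, all untested and inseparable in this design, and for falls such as CTGF, CYR61, CYP26A1 and BLVRA, which lack the match in the whole transcript, also effects downstream of YAP1 or of other matched genes.

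Genes with a 3' UTR match to the miR-302 family, abundant in human embryonic stem cells, differed from others by a log2 change of 0.0074 (SE 0.0105, permutation p = 0.470, 10000 permutations), below the 0.05 set before the test for relief from that family as a source of the rises. By site, t was -0.13 for AGCACTT and 2.39 (log2 difference 0.04) for GCACTTA. The share with a match was 35.1% among the 2089 risen genes and 31.9% in length-matched genes not past the threshold. Relief from the family thus stays open for a small part of the rises. TGCACTT, which shares 6 bases with both sites, had t = 6.21. However, ATGCACT and TGCACTA (t = 5.06 and 4.44) share TGCACT with it and lack those 6 bases. The t of TGCACTT is therefore not evidence for the family by itself. GC content and 3' UTR length bias between the groups had rho of -0.0451 and 0.0453 across genes. This is too small for a bias in a single direction across all genes to account for the rises. Risen and fallen genes both had longer 3' UTRs (medians 1729 and 1570 bases) than genes not past the threshold (1291). A link shared by rises and falls cancels in rho, so this test cannot exclude it. At the preset correlation, the lists of p53 and ATF4 targets passed also without genes holding the heptamer or its shifted form in the 3' UTR (camera adjusted p = 2.32e-05 and 0.00526). So did core and primed pluripotency (0.00447), cholesterol synthesis (0.00526), matrix and adhesion (0.0103) and the respiratory chain (0.0103). The Hippo list did not (0.543). Genes with a match only in the rest of the transcript stayed in these tests. With an estimated correlation, no list passed even with all genes. Whether these responses follow from AKAP13 loss, hairpin expression or doxycycline was not tested.

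The libraries numbered 1 deviated together from the means of their groups (r = 0.62 between their deviations across genes). A culture state lying along the treatment axis may be part of this: untreated library 1 minus 2 correlated with treated libraries 2 and 3 minus untreated library 3 at r = 0.0963 across genes, while treated library 1 minus 2 correlated with treated library 3 minus the untreated mean at r = 0.318, and genes are not independent replicates. Treated library 1 lay farthest along the first principal component, at 51.4, against 14.8 and 24.8 for treated libraries 2 and 3. The r of 0.318 therefore cannot tell a culture state from a larger response to treatment. A bias in GC content or 3' UTR length had rho of at most 0.140, in the untreated group, which leaves it open as a small part. The labels do not say what the numbers share, so a day, a passage or a batch cannot be told apart.

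For the count of 4617 genes, the 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split was the 1 split with that many, and the highest of the others gave 0 in limma (1328 at an unadjusted p under 0.05). Of the 4 splits that part all 3 pairs of replicate numbers, the other 3 gave 0 as well, with at most 51 at an unadjusted p under 0.05. Every split but the real one mixes treated and untreated libraries on both sides. The treatment difference then widens the spread within sides, so few calls were to be expected. These counts therefore do not tell how many of the 4617 calls are false.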
